A study of Mus musculus with 2 samples.

How the data were processed

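Both libraries were 5-prime single-cell libraries of sorted live CD8 T cells, 1 per group, each from a pool of mice. The deposited values were raw UMI counts per gene and barcode, made with Cell Ranger 7.0.0 per the file headers, on the mm10 build per the submitters' processing notes. Those notes also name R 4.4.2 and Seurat, without a role. The settings used to call barcodes as cells were not given in the sources used here. Both matrices held the same 32285 genes. Positions of 32235 of these were taken from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, by Ensembl ID, and 50 had none.

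Cells were kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs. This left out 1908 of 4927 parous barcodes and 15 of 2526 virgin barcodes, so the filter weighed far more on the parous library. Scrublet, run in scanpy 1.11.5 with an expected rate of 0.06, marked 2 parous and 12 virgin cells. At under 0.5% of each library the caller was taken not to have worked, and by the rule set beforehand its calls were kept, so keeping the calls, listed among the alternatives, gives the reported values.

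For clustering, virgin UMIs were thinned at random to 58.7% so that the median UMIs per cell matched. T cell receptor, immunoglobulin, ribosomal and mitochondrial genes were left out, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 0.8) were used without integration. A clustering without Gm42418, a transcript that overlaps ribosomal RNA, was run first. It departed from the design and was replaced by the planned one, and it is kept as an alternative. A cluster took the name of the type with most of its fixed markers at least 2-fold above the other cells and seen in at least 10% of its cells, with at least 3 needed. It stayed unnamed where its 10 leading genes held more markers of another type, or none of its own. The markers were fixed beforehand, and these naming thresholds were set after the data were seen. Clusters whose best type, with at least 3 markers, was not a CD8 T cell type were taken as other cells where they took that name or where under 75% of their cells had a Cd3e UMI. The NK or innate-like T cell type was not among these other types. A cluster of that name would have stayed among the CD8 T cells.

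UMIs were summed over the CD8 T cells of each library and divided by the total to give CPM. Log2 ratios had 0.5 added to each count. For 33 gene lists fixed beforehand, the median was taken over members with at least 10 UMIs and placed among 10000 random lists matched on expression in 20 bins. The adipocyte, fibroblast, endothelial and erythroid lists had under 3 measured members and gave no median, only summed CPM. Of 599 list entries 6 did not match a unique symbol in the matrix. Named genes were the 14 largest and the 14 smallest ratios among genes with at least 20 CPM and 30 UMIs in 1 library, without receptor segments, ribosomal, mitochondrial and unnamed genes, up to 6 members per list at least 1.5-fold apart, and a fixed set that included Itgae, Itga1 and Cd69. Within a class they were the 8 largest and the 8 smallest. Shares of cells with a UMI were compared after thinning each cell to 1400 UMIs, the 5th percentile of the shallower library rounded down. A Trbv gene was assigned with at least 2 UMIs and at least 2/3 of the cell's Trbv UMIs.

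The ratios and lists were tested on simulated counts drawn from the real means of the pooled comparison, with 200 of 13435 genes changed. The median recovered log2 ratio was 1.01 for genes changed 2-fold (true value 1) and 2.03 for genes changed 4-fold (true value 2), the intervals held the true ratio for 95.6% of genes, and 2 of 100 lists of unchanged genes fell outside the central 95%. Each gene was drawn as an independent Poisson count, as the intervals assume, so this checks the computation only. It does not cover UMIs that come from few cells or list members that are expressed together. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The alternatives covered scaling, weighting of cells, depth, cell filter, cells compared, resolution, genes clustered on and segment assignment. The designs, gene lists and most alternatives were fixed before the data were examined.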

Results

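Single-cell gene expression was measured in CD8 T cells sorted from the 4th mammary fat pad of C57BL/6 mice that had been through several pregnancies (parous) and of mice that had not (virgin). Each group was 1 library made from a pool of at least 5 mice, so no difference between the groups has a replicate check and no test was made. The intervals given are exact 95% intervals (Poisson for counts, Clopper-Pearson for shares) and cover counting error only, not differences between mice or between cell preparations. The parous library held 4927 barcodes and 14676415 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), and the virgin library 2526 barcodes and 20166425 UMIs. The cell filter kept 3019 parous and 2511 virgin cells, with medians of 4108 and 7001 UMIs per cell. Of these, 2990 parous and 2499 virgin cells lay in clusters of CD8 T cells and entered the comparisons. They included cluster 10 (160 parous and 47 virgin cells), which had little RNA (medians of 1278 and 2379 UMIs) and no marker of a cell type. Its leading genes included Gm26917 and AY036118, and a Trbv gene was assigned in 18.1% of its parous and 66.0% of its virgin cells. Without cluster 10 the median log2 ratio of the tissue residency list was 0.88 and that of the recirculation list -0.45.

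The first comparison asked whether parous mammary CD8 T cells carried more of the transcripts that mark tissue-resident memory T cells, which stay in a tissue and do not return to the blood. The parous library had more cells with RNA for the tissue-binding integrins. With every cell thinned to 1400 UMIs, Itgae, the alpha E integrin chain CD103 that binds E-cadherin, was found in 9.74% of parous cells (279 of 2866, interval 8.67 to 10.9%) and 3.10% of virgin cells (77 of 2485, interval 2.45 to 3.86%), a 3.14-fold higher share. Itga1, the collagen-binding integrin chain CD49a, was found in 9.32% of parous cells (267 cells, interval 8.28 to 10.4%) and 3.54% of virgin cells (88 cells, interval 2.85 to 4.34%), a 2.63-fold higher share. Without thinning, the shares were 18.8% and 10.6% for Itgae and 20.2% and 12.5% for Itga1. Thinning left out 124 parous and 14 virgin CD8 T cells with fewer UMIs. As background at the same 1400 UMIs, Itga1 was found in 0.418% of parous and in 0 of 986 virgin naive or central memory-like cells, where 3 cells would be 0.304%. Naive CD8 T cells do carry Itgae RNA, found in 5.22% of parous and 5.88% of virgin naive or central memory-like cells, which held 78.3% of all virgin Itgae UMIs. In the 28 parous cells of the cluster of other cells the shares were 7.14% for Itgae and 10.7% for Itga1, and the virgin library had too few such cells. A Cd8b1 UMI was found in 39.3% of these 28 cells, so they give no background free of T cell RNA. Outside 4 clusters that came almost wholly from the parous library, Itgae was found in 2.31% of parous and 2.67% of virgin cells, and Itga1 in 4.25% and 3.37%. Both Itgae and Cd69 were found there in 1.08% of parous and 1.65% of virgin cells.

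**Figure D1:**
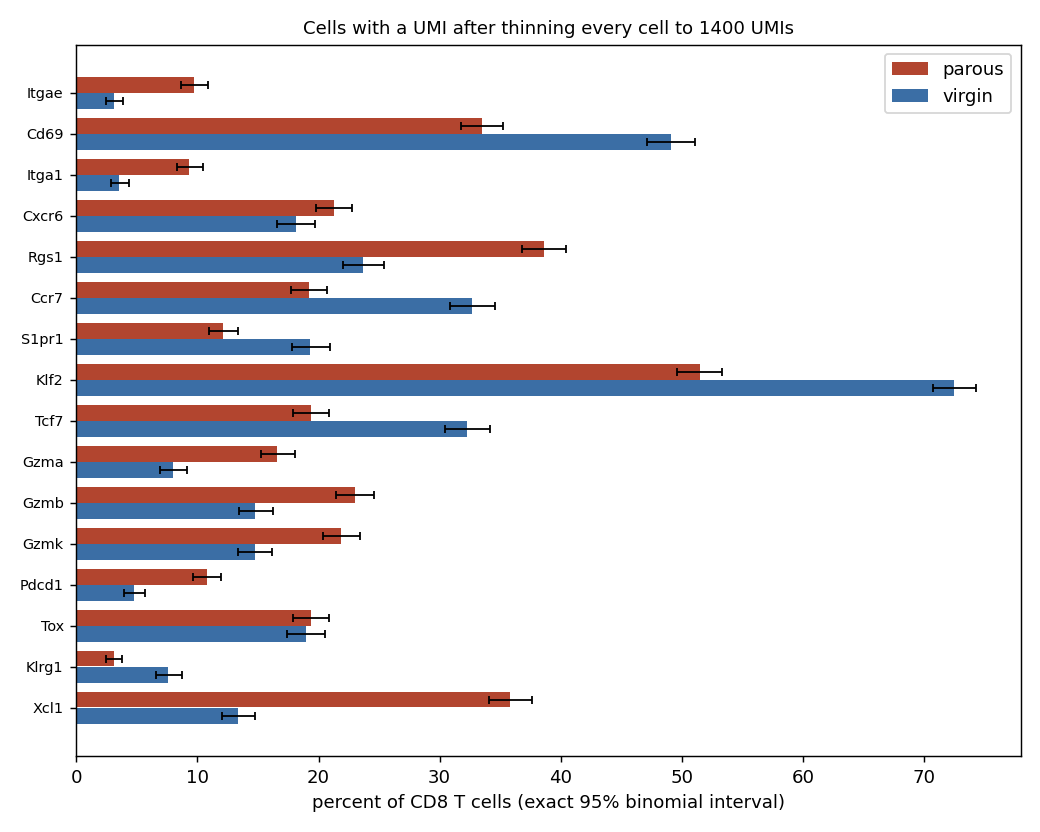
Percent of CD8 T cells with at least 1 UMI of each gene (horizontal axis) after every cell was thinned to 1400 UMIs, for the parous and the virgin library, 1 library each; bars are shares and whiskers exact 95% binomial intervals. Itgae, Itga1, Xcl1, Gzma and Pdcd1 were seen in more parous cells, and Ccr7, Klf2, Klrg1 and Cd69 in more virgin cells.

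In summed UMIs, 14 of the 25 measured members of the tissue residency list were at least 1.5-fold higher and 2 at least 1.5-fold lower in the parous library, with a median log2 ratio of 0.86, above that of nearly all of 10000 random lists matched on expression (percentile 100). Itgae (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446) stood at 85.1 CPM (UMIs of the gene per 1e6 UMIs of the library) in the parous and 20.3 CPM in the virgin library, 4.18-fold higher. Itga1 (chromosome 13, 114953096 to 115101964) was 2.41-fold higher, and Cdh1, which encodes E-cadherin, 12.8-fold higher. Litaf was 5.84-fold higher and the chemokine gene Xcl1 3.42-fold higher. Cxcr6, a chemokine receptor often used to mark resident cells, was 1.18-fold higher. Cd69, which encodes a surface protein that holds T cells in tissue, went the other way, with 340.8 CPM in the parous and 616.9 CPM in the virgin library. The 4 clusters that came almost wholly from the parous library held 85.1% of the parous Itgae UMIs and 73.6% of the parous Itga1 UMIs, and without them the list median was 0.04, and the log2 ratio was 0.04 for Itgae, -0.02 for Itga1, -0.33 for Cxcr6, 2.01 for Cdh1, 1.49 for Litaf and 0.86 for Xcl1.

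Several genes of killing and of innate-type receptors were higher in the parous library. Of the 16 measured members of the cytotoxic granule list 7 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.53 (percentile 100). Prf1, which encodes perforin, was found in 6.28% of parous and 6.76% of virgin cells at 1400 UMIs. Gzma, a granule protease, was 2.75-fold higher (1609.8 against 586.1 CPM) and Gzmb, another, 2.03-fold higher. The same 4 clusters held 87.2% of the parous Gzma UMIs (cluster 7 alone held 77.1%) and 80.7% of the parous Gzmb UMIs, and without them both genes were lower in the parous library, with log2 ratios of -0.94 for Gzma and -0.76 for Gzmb, and the list median was 0.08. Of the 22 NK receptor genes 15 were at least 1.5-fold higher and 3 at least 1.5-fold lower, with a median of 1.04 (0.45 without the 4 clusters). Within cluster 6 this list went the other way, with a median of -0.72, 1 of 12 members at least 1.5-fold higher and 7 lower. Its median was -0.15 in cluster 2 (15 members) and 0.16 in the naive or central memory-like class (7 members). Fcer1g and Tyrobp, signalling adaptors of innate receptors, were 18.1-fold and 13.4-fold higher. The 14 largest ratios ran from 25.7-fold for Gzmc to 4.82-fold for Lyn, a Src family kinase, and included Osgin1 (20.9-fold), Trf, which encodes transferrin (10.6-fold), and Car2, a carbonic anhydrase (5.66-fold). For Gzmc, a granzyme, 54.4% of the 428 parous UMIs came from 5 cells. Cluster 7 held 93.5% of the parous Gzmc, 80.5% of the Tyrobp and 74.3% of the Fcer1g UMIs. Without the 4 clusters these genes stayed higher in the parous library, with smaller log2 ratios of 1.23 for Gzmc, 2.003 for Tyrobp, 2.40 for Fcer1g, 2.16 for Osgin1, 2.11 for Trf, 1.10 for Lyn and 0.98 for Car2. Among inhibitory receptors Pdcd1, which encodes PD-1, was 2.18-fold higher, while Tox stood at 172 CPM in both libraries. That list had a median of 0.50, with 7 of 17 members at least 1.5-fold higher and 3 at least 1.5-fold lower. Without the 4 clusters its median was -0.25 and the log2 ratio of Pdcd1 0.47. The TGF-beta signalling list had a median of 0.42, with 8 of 18 members at least 1.5-fold higher, among them Pmepa1, and 0.08 without the 4 clusters (Pmepa1 1.42). Within cluster 6, which both libraries filled, its median was 0.50, with 7 of 16 members at least 1.5-fold higher and 0 lower. It was smaller in larger clusters that both libraries filled. The median was 0.11 in cluster 2, with 3 of 18 members higher and 0 lower. It was 0.10 in the naive or central memory-like class, with 1 of 18 higher and 3 lower.

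Genes of recirculating cells and of division, and some genes of circulating effector cells, were lower in the parous library. The recirculation list had a median log2 ratio of -0.45 (percentile 0), with 9 of 22 measured members at least 1.5-fold lower and 0 at least 1.5-fold higher. Ccr7, a chemokine receptor for lymph node entry, was 1.54-fold lower, and Klf2, a transcription factor that drives S1pr1, 2.07-fold lower. Without the 4 clusters the list median was -0.21, and the log2 ratio was -0.13 for Ccr7 and -0.75 for Klf2. The cell cycle list had a median of -1.07, with 22 of 26 members at least 1.5-fold lower. Of the 14 smallest ratios 5 were of cell cycle-linked histone genes of the Hist1 group, led by the linker histone gene Hist1h1b, 7.24-fold lower, and Ccna2, which encodes cyclin A2, was 4.45-fold lower. Klrg1 and S1pr5, markers of circulating effector cells, were 4.36-fold and 4.82-fold lower, and the circulating effector list had a median of -0.46, with 4 of 13 members at least 1.5-fold lower and 1, Gzma, higher. In the type I interferon list, with a median of -0.42, 10 of 30 members were at least 1.5-fold lower and 3 at least 1.5-fold higher. The smallest ratio belonged to the chemokine gene Ccl1, 37.1-fold lower, but its 501 virgin UMIs came from 10 cells and 317 of them from 1 cell. Its counting interval, which treats UMIs as independent, does not cover that. Spp1 was similar, with 302 virgin UMIs in 30 cells and 112 of them in 1 cell.

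**Figure D2:**
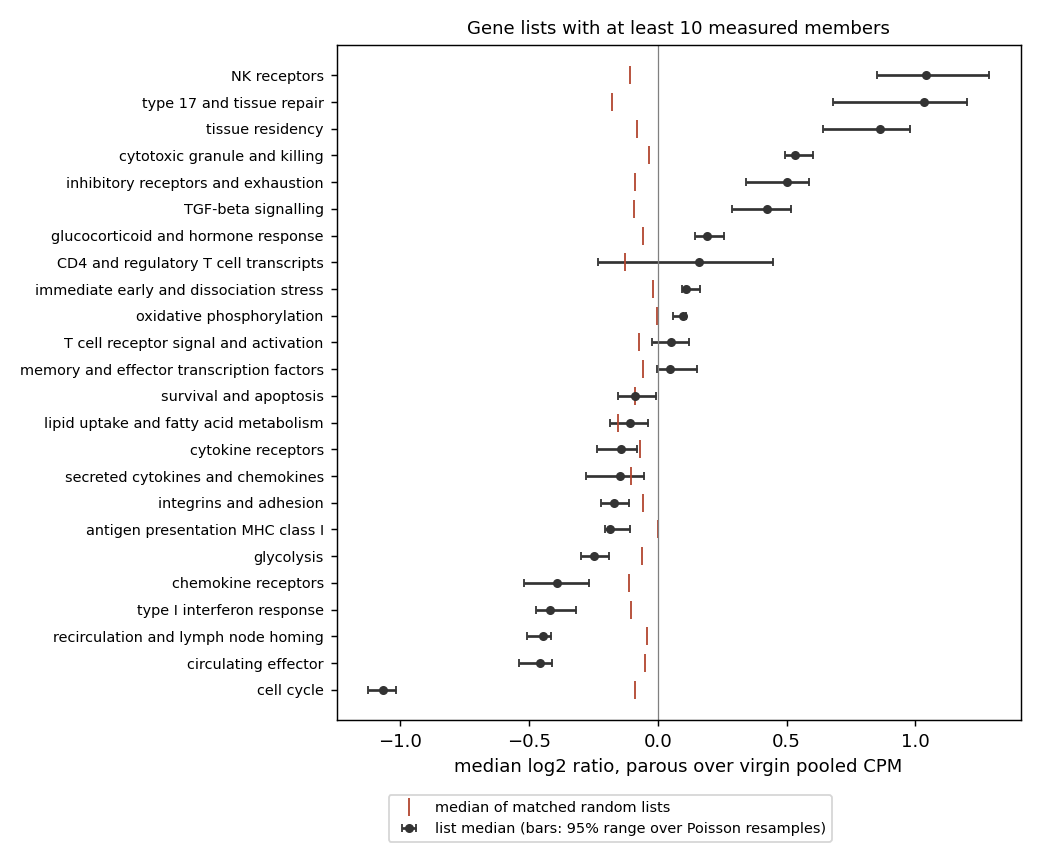
Median log2 ratio of parous over virgin CPM (horizontal axis) for each gene list with at least 10 measured members; points are list medians, bars the central 95% of 200 Poisson resamples of the counts, and red ticks the median of matched random lists. The NK receptor, type 17 and tissue residency lists lay highest, at 1.04, 1.03 and 0.86, and the cell cycle list lowest, at -1.07.

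Scaling by total UMIs left the median log2 ratio of all genes with at least 10 UMIs in each library at -0.13, and median-of-ratios scaling put it at 0.00, so log2 ratios within about that distance of 0 carry no direction. This held for the lists of survival and apoptosis genes (median -0.09) and of lipid uptake and fatty acid metabolism genes (median -0.11).

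Clustering divided the CD8 T cells into 13 clusters, plus 1 cluster of other cells. A naive or central memory-like cluster, marked by Ccr7, Lef1 and Dapl1, held 16.2% of parous cells (interval 14.9 to 17.6%) and 39.5% of virgin cells (interval 37.5 to 41.4%). Its share was lower in the parous library in every clustering run. Clusters named tissue-resident memory-like (5 and 6) held 16.6% of parous cells (interval 15.3 to 18.0%) and 5.92% of virgin cells (interval 5.03 to 6.92%). That class was not stable. Cluster 6, marked by P2rx7, Zfp683 and Ccr8, held 5.08% and 4.72% of the cells, and the difference lay in cluster 5, marked by Car2, Cdh1 and Itgae, with 344 of 2990 parous cells (11.5%) and 30 of 2499 virgin cells (interval 0.811 to 1.71%). Clustered without the residency, recirculation and marker genes, the class held 4.62% of parous and 4.08% of virgin cells, while 92.2% of cluster 5 stayed together in a cluster without that name, which held 20.5% of parous and 2.12% of virgin cells. At resolution 0.5 the class held 5.98% and 4.76%. Cluster 5 also stayed mostly together at resolution 1.2 (98.4%) and without Gm42418 (92.2%). Without thinning 59.4% of it lay in a cluster with 18.7% of parous and 3.40% of virgin cells. In 3 other clusterings its largest part lay in a cluster that both libraries filled. At resolution 0.5 this cluster took 52.7% of it and held 28.7% of parous and 29.4% of virgin cells. With the strict cell filter it took 48.9% and held 25.1% and 16.3%. Without doublet calls it took 64.7% and held 24.6% and 16.9%.

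Cluster 7, with Itgae in 76.2% and Itga1 in 71.4% of its cells, held 8.96% of parous cells (268 cells) and 0.0400% of virgin cells (1 cell). It had 7 of the resident markers at least 2-fold above the other cells, Zfp683 and Xcl1 among them. Its leading genes, such as Gzmc and Gzma, held more markers of NK or innate-like T cells (Tyrobp, Fcer1g and Klra7), so it stayed unnamed. Cd3e was found in 99.3% of its cells, Cd8a in 84.4% and Cd8b1, the beta chain of the CD8 receptor, in 24.5%. Over all parous CD8 T cells without thinning, Cd8a was found in 76.8% and Cd8b1 in 80.0%. Cluster 7 was thus poor in Cd8b1 RNA. Cluster 13, led by Klra1 and Ccr10, had 9 resident markers and held 1.34% of parous and 0.0400% of virgin cells. It stayed unnamed because its leading genes held a CD4 T cell marker, Trat1, and no resident marker. They held none of the fixed NK markers. Named from the number of markers alone, both joined the tissue-resident memory-like class, which then held 26.9% of parous and 6.00% of virgin cells. A Gzmk or exhausted-like cluster, marked by Pdcd1, Gzmk, Tigit and Lag3, held 12.2% of parous and 0.840% of virgin cells. Circulating effector-like cells were 2.31% of the parous and 6.72% of the virgin cells, and cycling cells 2.31% and 6.12%. With 1 library per group, a cluster that comes mostly from 1 library may mark that library and not a cell type.

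**Figure D3:**
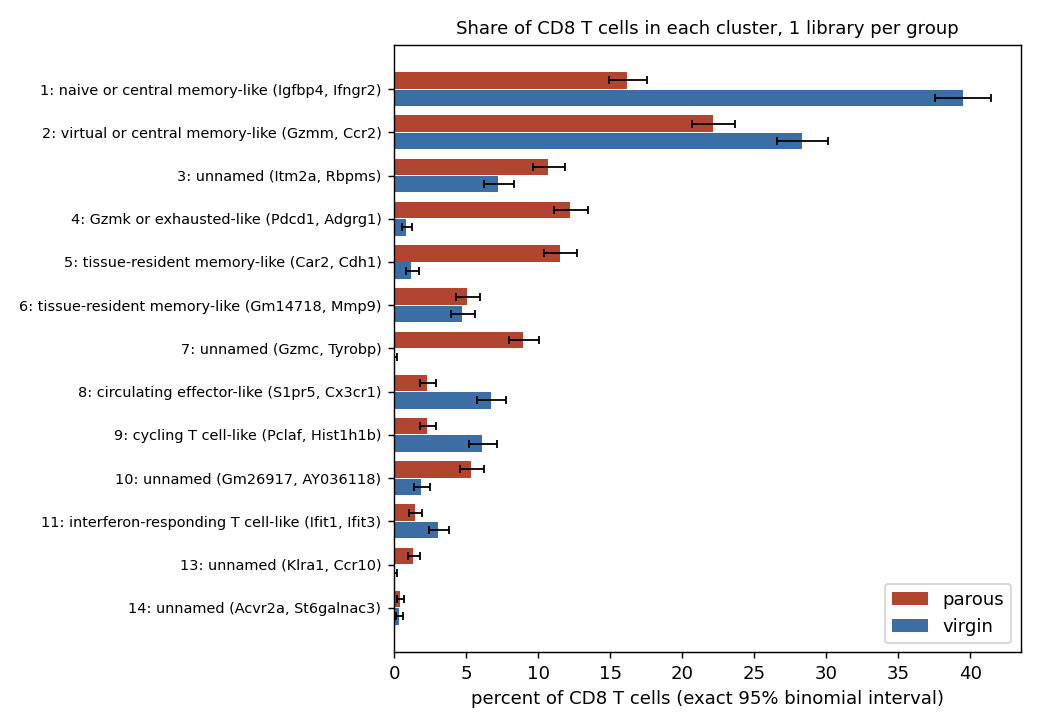
Percent of CD8 T cells in each cluster (horizontal axis) for the parous and the virgin library, 1 library each; whiskers are exact 95% binomial intervals, and each cluster is labelled with its name and its 2 leading genes. Clusters 4, 5, 7 and 13 came almost wholly from the parous library, and cluster 1 held 39.5% of virgin against 16.2% of parous cells.

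Within the naive or central memory-like class the recirculation list had a median log2 ratio of -0.18, with 0 of 21 measured members at least 1.5-fold higher and 2 at least 1.5-fold lower, and -0.06 with median-of-ratios scaling. Ccr7 was 1.13-fold higher in the parous cells of this class. Crem and Fosl2 were 3.03-fold and 2.55-fold higher, and Myc, a growth regulator, was 2.99-fold lower. The heat shock gene Hspa1b was 3.86-fold lower. Within the tissue-resident memory-like class, most parous cells came from cluster 5 and most virgin cells from cluster 6. The tissue residency list had a median of 0.07 there (0.33 with median-of-ratios scaling), with 9 of 25 members at least 1.5-fold higher and 6 at least 1.5-fold lower. The recirculation list was higher in the parous cells of this class, with a median of 0.32 (percentile 100), 9 of 20 members at least 1.5-fold higher and 2 at least 1.5-fold lower, and Ccr7 was 3.73-fold higher on 102 parous and 11 virgin UMIs. Within cluster 6 alone, which both libraries filled, its median was -0.05 (range over resamples -0.16 to 0.23). Gzma had 412 parous and 6 virgin UMIs in the class and was 27.6-fold higher, Pmepa1 was 6.75-fold and Itgae 2.74-fold higher, and Anxa1 was 8.72-fold lower. The residency genes Cd69, Cxcr6 and Itga1 were 2.73-fold, 1.82-fold and 1.46-fold lower.

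T cell receptor beta V segments were assigned in 2238 parous and 2148 virgin CD8 T cells. The effective number of Trbv genes on equal cell numbers was 14.8 in the parous and 16.0 in the virgin library. Trbv3 was the most common in the parous cells (12.3%) and Trbv29 in the virgin cells (9.36%). Cluster 13 used 1 segment for most of its cells, with Trbv12-1 in 23 of 27 assigned parous cells. In the virgin library Trbv31 made up 37.0% of the circulating effector-like cells with an assigned Trbv gene (51 of 138) and 39.6% of such cycling cells (55 of 139). It was also the most common in parous cycling cells (10 of 61, 16.4%). No cell had a UMI of Trav11 or Trav11d, segments of invariant NKT cells, where 3 cells of the total would be 0.100% of parous and 0.120% of virgin cells. These bounds suppose that the Trav segment is seen in each cell. A Trav gene was assigned in only 43 of the 106 virgin Trbv31 cells of these clusters. Assignment needed at least 2 UMIs, against 1 UMI for the Trav11 count. The share of cells in which 1 UMI would be seen is thus not known, and the absence sets no firm bound on invariant NKT cells. Trav1, the segment of mucosal-associated invariant T cells, had a UMI in 34 parous cells (1.14%, interval 0.789 to 1.58%) and 39 virgin cells (1.56%, interval 1.11 to 2.13%). A Trav1 UMI alone does not show that a cell is of that type.

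Few cells of other kinds passed the sort. The cluster of other cells, led by Fabp4, Cd74, Lyz2 and Apoe, held 0.961% of parous and 0.478% of virgin kept cells. A Cd4 UMI was seen in 0.174% of parous and 0.0402% of virgin CD8 T cells at 1400 UMIs, and Trdc, the delta chain constant gene of gamma-delta T cells, in 0.419% and 0.161%.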

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

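The tests of explanations in this part were chosen after the results were seen, except those on Trav pairing. Barcodes outside the comparisons carried T cell RNA in the parous library. Of the 1908 parous barcodes left out by the cell filter 915 had a Cd3e UMI, against 1 of 15 virgin barcodes. The cluster of other cells held 1174 casein UMIs (Csn1s1, Csn2 and Csn3) in 4 of 29 parous cells and 0 in 12 virgin cells, where 3 counts would be 12.3 CPM.

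Clusters 4, 5, 7 and 13 together held 34.0% of parous and 2.12% of virgin CD8 T cells, of which cluster 5 was not kept apart in each clustering (28.7% and 29.4% for the cluster that took the largest part of it at resolution 0.5). Cells without a T cell receptor, such as NK cells, are argued against by an assigned Trbv gene in 75.6% of these parous cells, against 74.4% of the other parous cells (79.4% without the low-RNA cluster 10). Depth differences left after the thinning of virgin UMIs are argued against by the shares among cells with like UMIs in the clustered counts, 38.7% of 1494 parous and 2.21% of 1268 virgin cells (17.5-fold). The cluster labels were made after that thinning and reused, so these shares do not judge other differences in library quality. Doublets are argued against by a median UMI count 0.909 times that of the other parous cells. Parity and a single mouse or cell preparation in the pool cannot be told apart with 1 library per group, and both may account for the pattern.

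Cd69 was 1.81-fold lower in the parous library although the tissue residency list was higher. Different cluster shares are argued against as the whole cause, because the median log2 ratio within 10 clusters was -0.65, with the interval below 0 in 6 clusters and above 0 in 1. A weaker immediate early response to cell handling in the parous library stays open, because that list's median of 0.11 lies over members that go both ways (quartiles -0.23 and 0.31), with Fos 1.83-fold and Jun 1.58-fold lower and Btg2 1.67-fold higher. Parity may also account for the pattern and was not tested apart from handling.

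Single Trbv genes were common in a few clusters, and expanded clones are a candidate explanation whose prediction, 1 Trav gene in at least 50% of such cells, was written before the result was seen. Among virgin Trbv31 cells of the circulating effector-like and cycling clusters 22 of 43 cells with an assigned Trav gene had Trav3-1 (51.2%, interval 35.5 to 66.7%), against 6.82% of other Trbv31 cells. Among parous Trbv12-1 cells of cluster 13 the share of Trav13-1 was 62.5% (5 of 8, interval 24.5 to 91.5%), against 5.22% of other Trbv12-1 cells. In the first set 16 further cells had Trav10d, and in the cluster 13 set the other 3 cells had Trav3-3. Both intervals lie above 20%, the bound written for no clones, and reach below 50%, the bound written for few clones. A Trav use without any common gene is thus argued against. The bounds concern 1 Trav gene and do not judge several together, so whether few clones make up these cells stays open.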

How the results depend on the processing

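The alternatives chosen after seeing the data were removing doublet calls, removing cells above 3 times the median UMIs, leaving out clusters, clustering without Gm42418 and naming from the number of markers alone. No paired analysis was possible because each group had 1 library. Of 1768 values of 136 named genes under alternatives 12 reversed, of 432 list medians 5 and of 326 within-class values 9. A further 293, 72 and 62 of these values moved outside their counting interval without being counted as reversed. So did 149 of 270 shares of cells with a UMI and 15 of 40 class shares. The alternative with doublet calls kept could change no value. The share of tissue-resident memory-like cells was higher and that of naive or central memory-like cells lower in the parous library in each of the 10 settings tried. These include doublet calls kept, which is the reported clustering. For tissue-resident memory-like cells the difference was small in several settings, the smallest being 5.94% against 5.70% with the strict cell filter. No cause was tested for the reversals or for these shares. The tissue residency median was 0.99 with median-of-ratios scaling, 1.01 as a mean over cells, 1.14 at 1400 UMIs, 1.05 without high-UMI cells and 0.039 without the clusters mostly of 1 library, and the recirculation median in the same settings was -0.32, -0.58, -0.58, -0.53 and -0.21, and -0.41 without ribosomal and mitochondrial genes. Without the clusters mostly of 1 library the inhibitory receptor median was -0.25, and log2 ratios were -0.94 for Gzma, -0.76 for Gzmb, -0.50 for Cd244a, -0.33 for Cxcr6, -0.33 for Trgv2, -0.16 for Cd3e, -0.044 for Epcam and -0.0195 for Itga1. With median-of-ratios scaling the lipid list was at 0.022 and the survival list at 0.041 (0.16 at 1400 UMIs). With all kept cells the MHC class II list was at 0.40, the Areg log2 ratio at -1.17, Tmem176b at -0.23 and H2-Ab1 at 0.21. That setting adds only the cluster of other cells, so these changes come from its cells. At 1400 UMIs Csn3 was at -0.21. The parous and virgin shares of tissue-resident memory-like cells were 5.98% and 4.76% at resolution 0.5, 6.65% and 4.20% without thinning, 4.62% and 4.08% without list and marker genes, 5.79% and 4.66% without doublet calls, 12.5% and 8.48% without high-UMI cells, and 5.94% and 5.70% with the strict cell filter. The parous share moved to 18.3% at resolution 1.2 and 26.9% with names from marker numbers, where the virgin shares were 5.92% and 6.00%. Naive or central memory-like shares were 20.1% and 41.6% at resolution 1.2. The parous and virgin shares with Itgae were 18.8% and 10.6% without thinning, 5.69% and 1.32% at 700 UMIs, and 12.2% and 4.55% at 2100 UMIs, and those with Itga1 were 20.2% and 12.5%, 5.62% and 2.16%, and at 2100 UMIs 11.9% in the parous library, with a share of cells with Itga1, virgin, percent of CD8 T cells, of 5.36%. Within tissue-resident memory-like cells, median-of-ratios scaling put the residency list at 0.33, inhibitory receptors at 0.015 (0.16 at 1400 UMIs), immediate early genes at 0.19 (0.036 at resolution 0.5) and NK receptors at 0.061 (0.27 at resolution 1.2). The memory and effector transcription factors list median log2 ratio within tissue-resident memory-like cells was 0.095 with that scaling and 0.000176 at resolution 0.5. Within naive or central memory-like cells the recirculation list was at -0.056 with median-of-ratios scaling and the residency list at 0.15 at resolution 1.2. The effective number of Trbv genes was 15.4 in the parous library with at least 1 UMI, and 13.2 in the parous and 15.3 in the virgin library with at least 4 UMIs.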

Other observations

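Further gene lists gave these values, to be read against the median of -0.13 over all genes. The type 17 and tissue repair list had a median log2 ratio of 1.03 (percentile 100), with 8 of 13 measured members at least 1.5-fold higher in the parous library and 0 at least 1.5-fold lower. Areg, an epidermal growth factor family ligand, had 118 parous UMIs in 59 cells and 22 virgin UMIs in 9 cells among CD8 T cells (log2 ratio 2.98). With all kept cells of any type the Areg log2 ratio was -1.17. That setting adds only the cluster of other cells (29 parous and 12 virgin cells), so the reversal comes from those cells and not from the CD8 T cells. The glucocorticoid and hormone response list had a median of 0.19, and the oxidative phosphorylation list 0.10. Medians were -0.25 for glycolysis, -0.39 for chemokine receptors, -0.19 for antigen presentation by MHC class I, -0.17 for integrins and adhesion, -0.14 for cytokine receptors and -0.15 for secreted cytokines and chemokines. They were 0.05 for T cell receptor signal and activation genes and 0.05 for memory and effector transcription factors.

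Lists of other cell types were measured in few members within the CD8 T cells. Medians were 1.44 over 5 members of the milk protein and epithelial list, 2.12 over 8 of the macrophage list, 1.82 over 6 of the gamma-delta list, 0.16 over 10 of the CD4 and regulatory list, -0.42 over 3 of the B cell list and -0.55 over 4 of the MHC class II list. The summed macrophage list was 71.5 CPM in the parous and 85.4 CPM in the virgin CD8 T cells, the opposite order to its median. Summed CPM, parous first, were 4.82 and 0.352 for the adipocyte list, 0.753 and 0.251 for the fibroblast list, 20.04 and 36.1 for the endothelial list, and 0.603 and 0.854 for the erythroid list. The endothelial value rests on 1 gene. Pecam1 held 262 of its 266 parous UMIs, in 213 cells, and 717 of its 718 virgin UMIs, in 491 cells.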
